A study of Mus musculus with 15 samples.

How the data were processed

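RNA of mouse spleen leukemic T cells was measured by RNA-seq in 15 libraries, 3 in each of 5 groups. Per the labels, bone marrow progenitors of Bcat1 wild-type or Bcat1 knock-out mice received ΔE-NOTCH1, a truncated NOTCH1 that signals without ligand, and were transplanted into irradiated C57BL/6J hosts. The groups were WT0 with vehicle, WT0 with the BCAT1 inhibitor ERG-245, WT6, KO7 and KO3, named by genotype and by the number in the labels (0, 0, 6, 7 and 3). Per the labels, RNA was extracted with the RNeasy kit and libraries were made with the TruSeq stranded mRNA kit. The inhibitor was injected intraperitoneally in 3 doses of 30 mg per kg, 8 h apart. The labels name PBS as treatment for all groups without ERG-245, whereas the alignment names in the file header of the 3 WT0 vehicle libraries contain DMSO. The study text speaks of 5 samples, and the labels do not state whether the 3 libraries of a group come from separate mice.

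The deposited table holds raw fragment counts per gene, with 39836 lines after the header. Per the file headers, the authors ran featureCounts 2.0.1 once per library on paired fragments with both ends mapped. Chimeric fragments were excluded, the minimum overlap was 25 bases, the strand setting was 2, and counts were taken over exons of the RefSeq annotation of GRCm38.p6. No option for multi-mapping reads stands in that command. The authors' processing notes name Trim Galore, STAR, Subread, DESeq2 and the build mm10, without settings. The deposited table also gives the length in bases of each gene's merged exons (its other unit), which was not used here. Counts were read for 39827 genes. Neb, Mycbp2 and Huwe1 were left out because their lines in the table were broken. A symbol was found for 39743 gene IDs and not for 84, and the start of 38575 matched genes was equal to that in the reference annotation. Each of the 15 value columns belonged to a sample of the series, with 0 columns of other samples.

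Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr by group (15948 genes), and libraries were scaled with TMM. A single quasi-likelihood fit to all 15 libraries (10 residual degrees of freedom) gave 5 comparisons between groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and the number that also changed at least 2-fold is given beside each count. Levels are CPM (counts scaled to the TMM-adjusted library total) as mean ± SD, and fold changes are log2 values from edgeR. Because the libraries of a group may share a leukemia, knock-out and wild type were also compared on counts summed per leukemia (KO7 and KO3 against WT6 and WT0 with PBS), with the same tools, 17226 genes and 2 residual degrees of freedom. The p-values of the 15-library fit measure the spread between libraries of a group, which may be technical.

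Before the data were examined, 34 gene lists were fixed: pathways around BCAT1, NOTCH1 and growth, stages of T cells, and markers of other cell types of the spleen. The list of mitochondrially encoded genes had no measured member, so 33 were tested. Each was tested with limma's camera against all other tested genes, with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Unless an estimated-correlation p is printed for a list that passed, its call held with that setting too. Of the 198 list results over all comparisons, 174 had the same numbers of members higher and lower when adjusted over the list alone as over all genes, and the others differed by at most 2 members. The lists overlap in places. Il2ra, Dtx1, Notch3 and Ptcra stand among both the NOTCH1 targets and the immature thymocyte genes. Btg2, Pmaip1, Slc7a11, Egln3, Ccr9, Ccr7, Cr2, Bax and Bbc3 are among the other genes that stand in more than 1 list.

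Named genes were chosen by a rule set before the data were examined. It takes Bcat1, the 10 genes per direction with the largest fold change among those past the threshold with a mean of at least 5 CPM over the libraries of both groups and no overlap between the groups' libraries, and up to 4 genes per list by smallest p. The first part leaves out gene models, pseudogenes, and T cell receptor, immunoglobulin and sex-linked genes, which are described as classes. It also takes the genes with the largest shared change in both knock-outs. Genes chosen after their values were seen are named as such. The overlap of both knock-out comparisons with WT6 was set against independent calls (the product of both counts over all genes, per direction). It was also set against 20 simulations each of unchanged groups compared with the same WT6 libraries, with the spread between libraries or with that between leukemias. Shares of T cell receptor beta V segments (TRBV) and marker shares were described without a test.

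Total counts per library were 17441292 to 28902573. A count of 0 in a group allows up to 3 counts of its total, which covers counting error only. On simulated counts with the spread between libraries of a group, edgeR recovered 65.7% of genes changed 1.25-fold, 88.1% at 1.5-fold and 98.5% at 2-fold, with 7 false calls among 15563 genes. With the spread between leukemias it recovered 1.49% at 2-fold, 47% at 4-fold and 74.2% at 8-fold, with 15 false calls among 16846 genes, and DESeq2 made 115 false calls among 17226. Camera recovered a list shifted 1.2-fold, and it called 1 unchanged list with the preset correlation and 0 with the estimated one. Genes were simulated independently with the spread between libraries, so these calls do not measure how camera behaves with correlated genes.

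Alternatives covered DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, each group pair alone, the replicate number as a block, and each replicate left out. Across leukemias they also covered libraries as replicates, the leukemia as a random block and each leukemia left out. Others were added after seeing the data: a fit without receptor, immunoglobulin and other-cell marker genes, the ERG-245 libraries in place of the PBS ones across leukemias, and ERG-245 as a single sum tested against the sums of both wild-type leukemias with the spread between leukemias. Residuals of libraries that share a replicate number in different groups correlated across genes at r of -0.0462 to 0.0321 over 30 pairs, so the number was not used as a block in the fit. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.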

Results

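Gene expression was measured in 15 RNA-seq libraries of spleen leukemic T cells from mice carrying ΔE-NOTCH1 leukemias, with 3 libraries in each of 5 groups. The groups were WT0 treated with PBS, WT0 treated with the BCAT1 inhibitor ERG-245, the wild-type leukemia WT6, and the Bcat1 knock-out leukemias KO7 and KO3, where the labels give PBS as the treatment of WT6, KO7 and KO3 too. Total counts were 17441292 to 28902573 per library, with group means of 21026000 in WT0 with PBS, 20378000 in WT0 with ERG-245, 24999000 in WT6, 18468000 in KO7 and 20841000 in KO3. Between 19679 and 20968 genes were detected per library. Libraries of the same group correlated at r of 0.993 to 0.996 across genes and those of different groups at 0.94 to 0.965 (genes are not independent replicates). The biological coefficient of variation was 2.18% between libraries of a group and 41.9% between leukemias of a genotype. The p-values of comparisons between groups therefore measure the spread between libraries, which may be technical. Shares of neutrophil markers had SDs of 5.71e-05% to 0.001275% of counts within groups, against means of 0.000954% to 0.0384% among groups. This closeness argues against separate mice within a group, though the labels do not say.

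**Figure D1:**
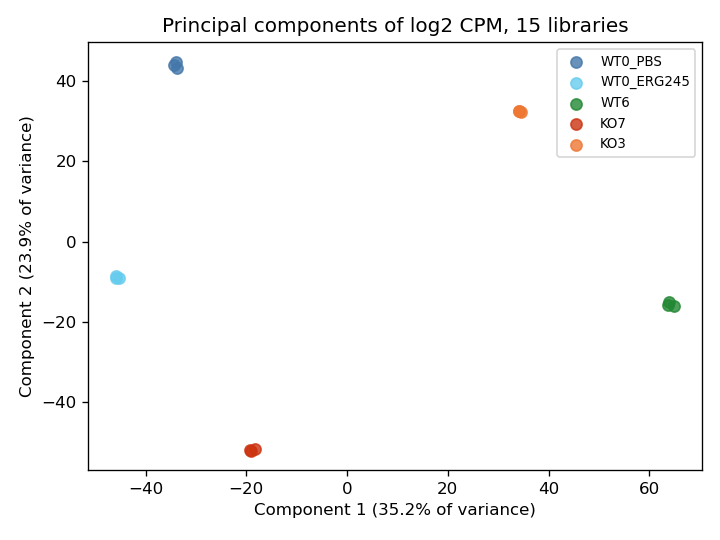
Principal components 1 (35.2% of the variance) and 2 (23.9%) of log2 CPM in the 15 libraries. Each point is a library, and the 3 libraries of each of the 5 groups lie close together.

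To evaluate the target itself, the level of Bcat1, the cytosolic branched-chain aminotransferase that moves the amino group of leucine, isoleucine and valine to 2-oxoglutarate, was compared among groups. Bcat1 (gene ID 12035) lies on chromosome 6 from 144993835 to 145076157 of GRCm38, and its counts cover the exons of the whole gene. Its level was 17.8 ± 0.952 CPM (SD, n = 3) in WT0 with PBS and 35.2 ± 0.415 CPM in WT6. In KO7 it was 2.09 ± 0.596 CPM, 5.92% of WT6 and 11.7% of WT0 with PBS, from 26 to 47 counts per library. In KO3 it was 6.95 ± 0.845 CPM, 19.7% of WT6 and 39% of WT0 with PBS, from 132 to 170 counts per library. Against WT6, Bcat1 fell in KO7 (log2 -4.07, SE 0.10, edgeR adjusted p = 8.9e-49) and in KO3 (log2 -2.34, SE 0.078, edgeR adjusted p = 6e-41). It was higher in KO3 than in KO7 (log2 1.73, edgeR adjusted p = 7.03e-18). With ERG-245, Bcat1 fell to 13.3 ± 0.772 CPM (log2 -0.42, SE 0.08, edgeR adjusted p = 4.34e-06).

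**Figure D2:**
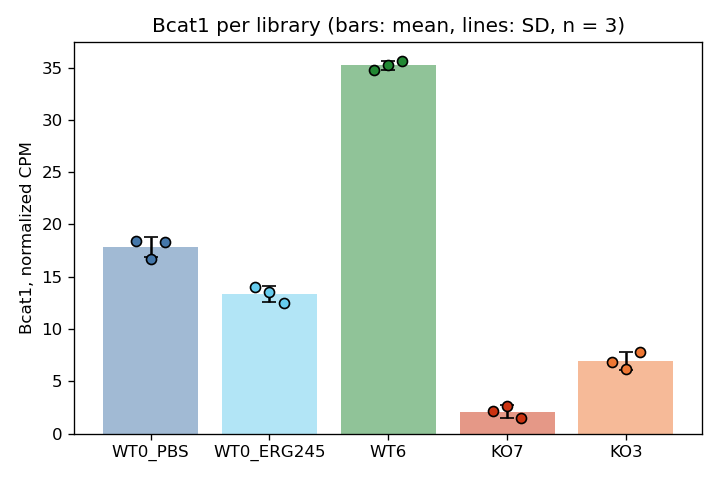
Bcat1 level in normalized CPM for the 5 groups. Bars show the mean, error bars the SD and points the 3 libraries of each group, with KO7 at 2.09 and KO3 at 6.95 CPM against 35.2 in WT6.

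T cell receptor beta segments, which each T cell clone rearranges in its own way, differed in every group. Trbv17 held 39.7 ± 0.855% of TRBV counts in WT0 with PBS (SD, n = 3) and 0.93 ± 0.19% in WT0 with ERG-245, where Trbv16 led with 49.9 ± 1.19%. Trbv16 held 4.92% in the PBS libraries. The leading segment was Trbv19 in WT6 (54.4 ± 0.52%), Trbv5 in KO7 (79.1 ± 0.855%) and Trbv15 in KO3 (85.6 ± 0.339%). Sex-linked genes also differed. Xist, the RNA of the inactive X chromosome, stood at 4373 CPM in WT0 with PBS, 2991 with ERG-245, 322.5 in WT6, 108 in KO7 and 212 in KO3. The Y-linked Ddx3y, an RNA helicase, had 0 counts in WT0 with PBS, which allows up to 0.0476 CPM over the group. It stood at 0.434 CPM with ERG-245, 88.1 in WT6, 68.0 in KO7 and 69.4 in KO3.

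**Figure D3:**
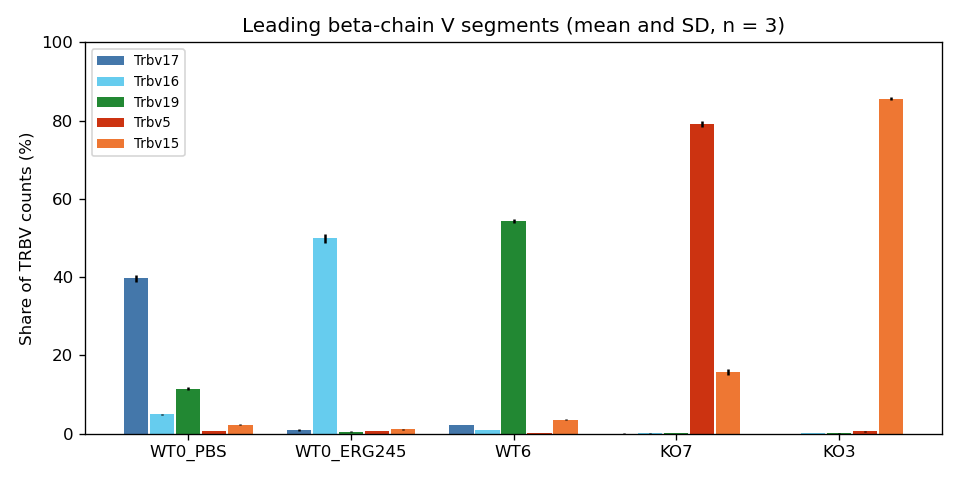
Share of TRBV counts in percent held by the leading segments in each of the 5 groups. Trbv17 leads in WT0 with PBS at 39.7%, and Trbv16 leads in WT0 with ERG-245 at 49.9%.

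Transcripts of other spleen cells were present at different shares. Erythroid markers took 4.05% of counts in WT0 with PBS, 4.72% with ERG-245, 1.26% in WT6, 5.83% in KO7 and 1.15% in KO3. Immunoglobulin genes took 0.246%, 0.794%, 2.63%, 0.794% and 0.795% in the same order of groups. Macrophage and monocyte markers took 0.139%, 0.18%, 0.235%, 0.405% and 0.18%. Neutrophil markers took 0.00782%, 0.000954%, 0.0384%, 0.0147% and 0.0207%.

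To evaluate what inhibition of BCAT1 changes in a leukemia with intact Bcat1, WT0 leukemia under ERG-245 was compared with PBS. Trbv17 held 39.7% of TRBV counts with PBS and 0.93% with ERG-245. Any difference given below may therefore belong to the leukemic clone and not to the inhibitor. All 48 measured genes of oxidative phosphorylation rose with ERG-245 (median log2 0.35, camera adjusted p = 6.79e-13). Ndufb8, a subunit of respiratory complex I, rose from 108 ± 3.74 to 175 ± 1.77 CPM (SD, n = 3), and Cox4i1, a subunit of cytochrome c oxidase, from 397 to 542 CPM. Of 21 NRF2 and redox genes, 16 rose and 2 fell (camera adjusted p = 0.000331). The quinone reductase Nqo1 rose by log2 2.15, the sulfiredoxin Srxn1 by 2.13, and Gpx4, which reduces lipid peroxides, by 0.89. Of 30 histone acetylation genes, which write, read or remove acetyl marks, 22 fell and 2 rose (camera adjusted p = 0.000786). Among them were the deacetylase Hdac7 (log2 -0.53) and the acetyltransferase Kat6a (-0.49).

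Interferon response genes moved mostly upward, with 21 of 35 higher and 4 lower over all genes, and 23 and 4 adjusted over the list alone (median log2 0.25, camera adjusted p = 0.000621). Ifit1, an antiviral RNA-binding protein, rose from 12.4 to 54.4 CPM and Ifi35 from 31.1 to 101 CPM. Among MHC class I presentation genes, 11 of 14 rose and 0 fell (camera adjusted p = 0.00102, adjusted p = 0.0693 with an estimated correlation), with H2-D1 up by log2 0.60. Of 18 NOTCH1 targets 13 fell and 3 rose (median log2 -0.62, camera adjusted p = 0.000616, adjusted p = 0.0656 with an estimated correlation). Il7r, the receptor of the T cell growth factor IL-7, fell from 80.0 to 23.2 CPM, Il2ra from 498 to 235 CPM, Heyl from 198 to 92.6 CPM and Notch1 from 1316 to 823 CPM. Of 21 immature thymocyte genes 11 fell and 7 rose (camera adjusted p = 0.0385, adjusted p = 0.0693 with an estimated correlation and 0.0514 with a replicate block), with Gata3, a T-lineage transcription factor, down by log2 -1.27.

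Branched-chain amino acid catabolism rose in 14 of 27 genes and fell in 5 (median log2 0.18, camera adjusted p = 0.0295, adjusted p = 0.0656 with an estimated correlation). Bcat2, the mitochondrial aminotransferase, rose from 54.3 to 77.1 CPM and Acat1, which acts late in isoleucine breakdown, from 89.3 to 126 CPM. Of 27 genes of the ATF4 stress response, 17 rose and 5 fell, and 18 and 5 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.0656 with an estimated correlation). The asparagine synthetase Asns rose by log2 0.81 and Ddit4, an inhibitor of mTORC1, by 0.89, while the transcription factor Cebpg fell (log2 -0.79). Unfolded protein response genes rose in 12 of 17 and fell in 3 (camera adjusted p = 0.0176, adjusted p = 0.07 with an estimated correlation), and S phase genes rose in 16 of 25 and fell in 5 (camera adjusted p = 0.0193, adjusted p = 0.0579 with an estimated correlation). Beside the unfolded protein response, the immunoglobulin share of counts rose from 0.246% to 0.794%, although 12 of 15 B cell markers fell. The 2-oxoglutarate dioxygenases, enzymes that use the keto acid BCAT1 consumes, fell in 14 of 26 and rose in 3 (camera adjusted p = 0.0193, adjusted p = 0.0693 with an estimated correlation), with the demethylase Kdm5c down by log2 -0.53. Kdm5c lies on the X chromosome, and Xist was lower with ERG-245 too (2991 against 4373 CPM).

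Markers of other cells moved both ways. All 9 platelet markers fell (median log2 -3.97, camera adjusted p = 8.76e-07), as did 10 of 13 neutrophil markers (median log2 -3.43, camera adjusted p = 2.81e-05). The chemokine Ppbp fell (log2 -5.20), as did the calprotectin subunit S100a9 (log2 -4.38). All 11 stromal and endothelial markers rose (camera adjusted p = 0.000117), as did 12 of 14 erythroid markers with 0 lower (camera adjusted p = 0.000331). The collagen Col3a1 rose by log2 1.16 and the carbonic anhydrase Car1 by 1.02. Of 15 B cell markers 12 fell and 2 rose (camera adjusted p = 0.00195, adjusted p = 0.0693 with an estimated correlation). Among them the light chain Igkc rose (log2 1.95). Macrophage markers rose in 11 of 17 and fell in 3 (camera adjusted p = 0.0132, adjusted p = 0.0935 with an estimated correlation), and dendritic cell markers fell in 8 of 12 and rose in 3 (camera adjusted p = 0.0212, adjusted p = 0.0935 with an estimated correlation).

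Among genes with a mean of at least 5 CPM that are not receptor, immunoglobulin or sex-linked genes or unnamed gene models, the largest increases with ERG-245 included Mcpt2 and Mcpt4, mast cell proteases (log2 8.06 and 4.18), Oas1e, a member of the oligoadenylate synthetase family (6.18), Prdm16, a transcription factor (4.04), and the chemokine Ccl8 (3.68). Mcpt2 went from 0.395 ± 0.117 to 109 ± 4.29 CPM (SD, n = 3, edgeR adjusted p = 2.23e-66). The largest decrease among these was in Prss2, an anionic trypsinogen, from 123 ± 3.21 to 2.04 ± 0.526 CPM (log2 -5.91, edgeR adjusted p = 1.9e-64). The gap junction gene Gjc1 (log2 -4.58), the sodium-proton exchanger Slc9a2 (-4.25) and the gluconeogenic enzyme Fbp1 (-3.97) fell too. In all, 5263 genes rose and 5225 fell by edgeR, of which 905 and 965 changed at least 2-fold. The other 14 lists had camera adjusted p from 0.107 to 0.861, among them MYC and ribosome biogenesis (0.505), p53 targets (0.791), G2 and M phase (0.155), cholesterol synthesis (0.843) and amino acid transporters (0.352). Mature T cell genes had a median log2 of -0.12 and a mean of 0.11, and the direction of camera was downward (camera adjusted p = 0.861). The PBS and ERG-245 libraries differ in their leading TRBV segment, so treatment is not the only difference between them.

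To evaluate the loss of Bcat1, each knock-out leukemia was compared with the wild-type leukemia WT6, beginning with KO7. Unfolded protein response genes, which fold and clear proteins in the endoplasmic reticulum, fell in 16 of 17 members with 0 higher (median log2 -0.62, camera adjusted p = 4.28e-08). The chaperone Hsp90b1 fell from 1067 ± 38.2 to 421 ± 9.39 CPM (SD, n = 3), and the disulfide isomerase Pdia4 (log2 -1.37) and the transcription factor Xbp1 (-0.90) fell as well. Antibody-secreting cells also express these genes at high levels, and the immunoglobulin share of counts fell alongside, from 2.63% in WT6 to 0.794% in KO7, with Igkc from 5791 to 1485 CPM. Cell division genes rose in KO7, with 21 of 27 G2 and M phase genes higher and 3 lower (camera adjusted p = 1.92e-05) and 18 of 25 S phase genes higher and 6 lower (camera adjusted p = 0.00408). The proliferation marker Mki67 and the ribonucleotide reductase subunit Rrm2 each rose by log2 0.83. Rrm2 stood at 346 CPM in WT6 and 615 in KO7, but at 631 CPM in the wild-type WT0 with PBS. Of 35 interferon response genes 25 rose and 6 fell (camera adjusted p = 7.35e-06), with Rsad2, an antiviral enzyme, from 72.3 to 326 CPM and the ubiquitin-like Isg15 from 32.9 to 129 CPM. Rsad2 stood at 361 CPM in WT0 with PBS. Genes of G2 and M phase (camera adjusted p = 0.152), S phase (0.998) and the interferon response (0.342) did not pass across leukemias.

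Redox genes of the NRF2 list rose in 16 of 21 and fell in 3 (camera adjusted p = 0.000291), with the glutathione peroxidase Gpx1 up by log2 1.93 and the heme oxygenase Hmox1 by 1.82. Across leukemias the NRF2 list passed camera with the preset correlation (adjusted p = 0.0292) but not with the estimated one (0.999). Beside these lists, all 14 erythroid markers rose (median log2 2.34, camera adjusted p = 1.24e-12), with the heme synthesis enzyme Alas2 from 333 to 2106 CPM and the anion exchanger Slc4a1 from 552 to 3197 CPM. Macrophage and monocyte markers rose in 13 of 17 and fell in 4 (camera adjusted p = 8.36e-05). Cd5l, secreted by tissue macrophages, rose (log2 2.46) and the lysozyme Lyz2 fell (log2 -2.95). Neutrophil markers fell in 11 of 13 and rose in 1 (camera adjusted p = 0.000651), and dendritic cell markers, which include Ccr9 of the mature T cell list, fell in 10 of 12 and rose in 1 (camera adjusted p = 0.00201). Mature T cell genes fell in 20 of 24 and rose in 3 (camera adjusted p = 0.00105), with the gut-homing receptor Ccr9 down by log2 -2.27 and Cd4 up by 1.07. WT6 had 18 of 24 of these genes higher and 5 lower than the wild-type WT0 with PBS. Across leukemias their median log2 was 0.075 with camera's direction upward (camera adjusted p = 0.762). B cell markers fell in 11 of 15 and rose in 2 (camera adjusted p = 0.00408, adjusted p = 0.115 with an estimated correlation).

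MYC and ribosome biogenesis genes fell in 19 of 28 and rose in 4 (camera adjusted p = 0.0266, adjusted p = 0.0515 with an estimated correlation), although the transferrin receptor Tfrc, which also serves red cell precursors, rose by log2 1.46. Oxidative phosphorylation rose in 26 of 48 and fell in 6 (camera adjusted p = 0.0111, adjusted p = 0.397 with an estimated correlation). Branched-chain amino acid catabolism had a median log2 of 0.04, a mean of -0.11 and a camera adjusted p of 0.871. NOTCH1 targets had a camera adjusted p of 0.269, though the transcription factor Hes5 fell (log2 -2.77). The other 18 lists had camera adjusted p from 0.0915 to 0.968, including amino acid transporters (0.0915), the ATF4 stress response (0.158), 2-oxoglutarate dioxygenases (0.248) and histone acetylation (0.871). Among dioxygenases, Tet1, which oxidizes methylcytosine, fell (log2 -2.95). Heat shock genes (median log2 -0.07, mean 0.24), stromal markers (0.17 and -0.05) and histone acetylation genes (0.01 and -0.06) had medians and means of opposite sign. Among the genes with a mean of at least 5 CPM, leaving out receptor, immunoglobulin and sex-linked genes and gene models, the largest increases were in Hormad2, a meiotic chromosome protein (log2 6.42), the claudin Cldn4 (3.74) and Cyp39a1, an oxysterol hydroxylase (3.53). The largest decreases among them were in the serotonin receptor Htr4 (log2 -7.44), Retnla, a product of alternatively activated macrophages (-4.88), Srgap3 (-4.71) and the arginine deiminase Padi4 (-4.37). In all, 5143 genes rose and 5849 fell by edgeR, of which 1481 and 1303 changed at least 2-fold.

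In KO3, as compared with WT6, unfolded protein response genes fell in all 17 members (median log2 -0.60, camera adjusted p = 7.83e-10), with Hsp90b1 down from 1067 ± 38.2 to 638 ± 14.0 CPM (SD, n = 3). The immunoglobulin share fell here too, from 2.63% to 0.795% of counts, with Igkc from 5791 to 1563 CPM. The ATF4 stress response fell in 22 of 27 genes and rose in 1 (median log2 -0.38, camera adjusted p = 2.5e-05). Pycr1, an enzyme of proline synthesis, fell from 11.4 to 2.84 CPM and Asns from 49.5 to 29.6 CPM. MYC and ribosome biogenesis genes rose in 25 of 28 and fell in 1 (median log2 0.25, camera adjusted p = 2.32e-07), with the ribosome assembly factor Wdr12 up by log2 0.57 and nucleophosmin Npm1 by 0.37. S phase genes rose in 22 of 25 with 0 lower (camera adjusted p = 7.29e-07), with the replication helicase subunit Mcm6 up by 0.35. Across leukemias the ATF4 stress response (camera adjusted p = 0.897), MYC and ribosome biogenesis (0.998) and S phase genes (0.998) did not pass. WT6 itself differed from the wild-type WT0 with PBS, with 22 of 27 ATF4 genes higher, 24 of 25 S phase genes lower and 16 of 28 MYC genes lower.

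Some metabolic lists rose by small amounts in KO3, while cholesterol synthesis (camera adjusted p = 0.28) and amino acid transporters (0.775) did not pass. Branched-chain amino acid catabolism rose in 19 of 27 genes and fell in 1, which was Bcat1 itself (median log2 0.22, camera adjusted p = 0.000927). Bckdha, a subunit of the branched-chain ketoacid dehydrogenase, rose from 35.1 to 52.4 CPM. Glycolysis and hypoxia genes rose in 15 of 26 and fell in 4 (camera adjusted p = 0.00362), with the stress-responsive Ndrg1 from 38.8 to 210 CPM. Ndrg1 stood at 214 CPM in the wild-type WT0 with PBS, and the list did not pass across leukemias (camera adjusted p = 0.497). TCA cycle and glutamate genes rose in 15 of 28 and fell in 3 over all genes, and 17 and 3 adjusted over the list alone (median log2 0.08, camera adjusted p = 0.00478), with the isocitrate dehydrogenase Idh2 up by log2 0.95. Oxidative phosphorylation rose in 35 of 48 and fell in 2, and 36 and 2 adjusted over the list alone (camera adjusted p = 5e-06, adjusted p = 0.104 with an estimated correlation). Redox genes of the NRF2 list rose in 13 of 21 and fell in 5, and 15 and 5 adjusted over the list alone (camera adjusted p = 0.0224, adjusted p = 0.114 with an estimated correlation).

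Targets of p53 fell in 17 of 26 and rose in 2 (camera adjusted p = 0.00434), with the antiproliferative gene Btg2 down by log2 -0.58. Btg2 stood at 447 CPM in WT6 and 300 in KO3, but at 273 in the wild-type WT0 with PBS and 601 in KO7. Across leukemias p53 targets had a median log2 of -0.018 and did not pass (camera adjusted p = 0.897). Immediate early genes fell in 16 of 20 and rose in 2 (camera adjusted p = 0.00336, adjusted p = 0.0904 with an estimated correlation), with the nuclear receptor Nr4a1 down by -1.40 and Jun up by 1.68. DNA repair genes rose in 18 of 33 and fell in 4 (camera adjusted p = 0.0114, adjusted p = 0.154 with an estimated correlation), and interferon response genes rose in 16 of 35 and fell in 8 (camera adjusted p = 0.0303, adjusted p = 0.054 with an estimated correlation). Beside these lists, dendritic cell markers fell in 11 of 12 with 0 higher (camera adjusted p = 1.03e-05), neutrophil markers in 12 of 13 with 0 higher (camera adjusted p = 0.00124), and stromal markers in 8 of 11 with 1 higher (camera adjusted p = 0.00434). The invariant chain Cd74 (log2 -1.14) and the antimicrobial peptide gene Camp (-1.63) were among those that fell. B cell markers fell in 10 of 15 and rose in 1 (camera adjusted p = 0.00362), and macrophage markers fell in 11 of 17 and rose in 2 (camera adjusted p = 0.00478), each with an adjusted p = 0.0904 with an estimated correlation. Erythroid markers had a camera adjusted p of 0.28.

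Immature thymocyte genes had a median log2 of -0.10, a mean of 0.10 and a camera adjusted p of 0.471. Within that list Dntt, the terminal transferase of receptor rearrangement, rose by log2 1.43 and the recombinase subunit Rag2 by 1.84. NOTCH1 targets had a median log2 of -0.04 while camera's direction was upward (camera adjusted p = 0.879). The other 12 lists had camera adjusted p from 0.0643 (BCL2 family) to 0.879, including G2 and M phase (0.495), mature T cell genes (0.429) and amino acid transporters (0.775). With receptor, immunoglobulin and sex-linked genes and gene models again left out, the largest increases among genes with a mean of at least 5 CPM were in Acan, a cartilage proteoglycan (log2 5.13), Cpsf4l (4.08) and Cldn4 (3.81). The largest decreases among them were in Mtus2 (log2 -7.09), Srgap3 (-5.05), the neurotrophin receptor Ntrk3 (-4.78), Mn1 (-4.59) and the surface antigen Ly6d (-4.52). In all, 4421 genes rose and 5101 fell by edgeR, of which 644 and 1189 changed at least 2-fold.

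**Figure D4:**
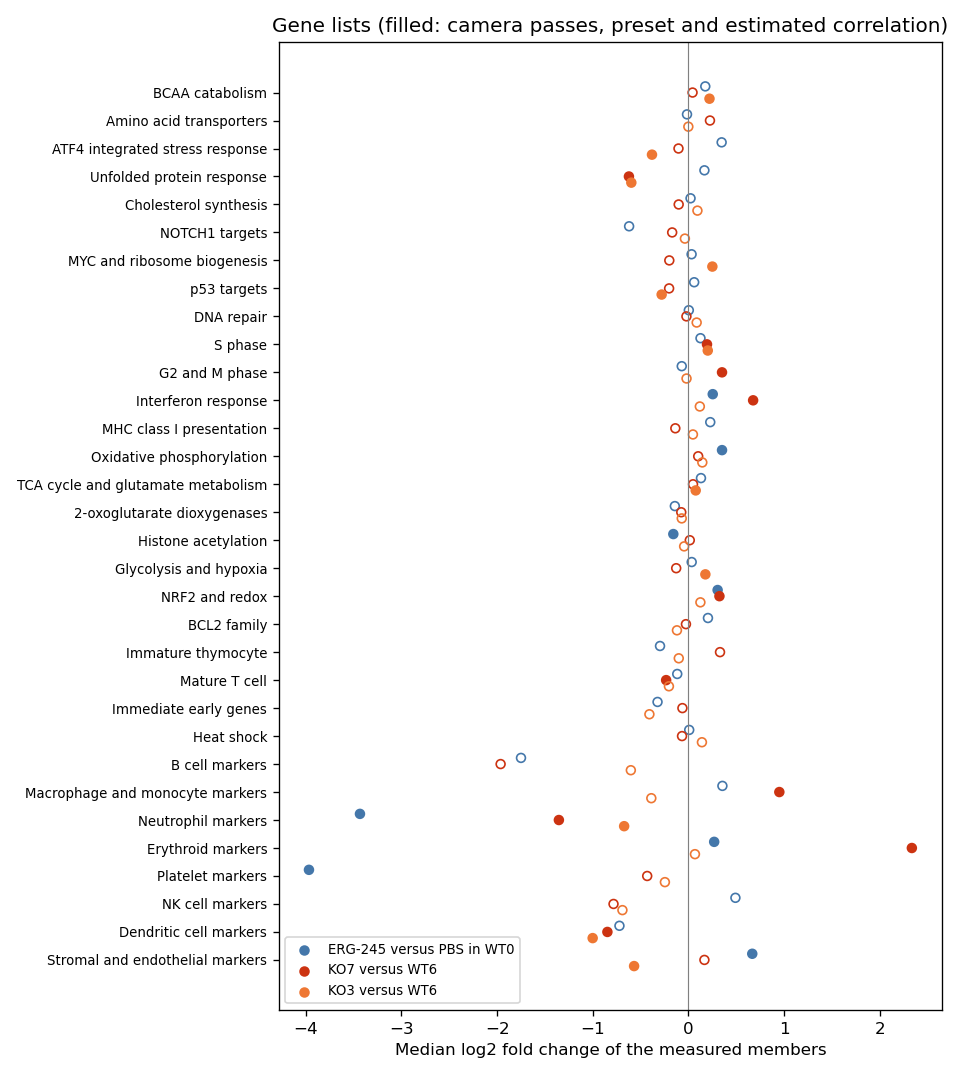
Median log2 fold change of 32 gene lists in 3 comparisons (ERG-245 against PBS, KO7 against WT6 and KO3 against WT6). Filled points mark lists that passed camera with both the preset and the estimated correlation, as the erythroid markers did in KO7 with a median of 2.34. Both knock-out comparisons share the WT6 libraries.

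The genes changed in both knock-outs relative to WT6 were then counted. Cldn4 rose from 2.67 CPM in WT6 to 35.8 in KO7 and 37.6 in KO3, and Ace, the angiotensin-converting enzyme, from 21.0 to 145 and 124. Ifi208, an interferon-inducible gene, Mid1, a ubiquitin ligase, and the class I gene H2-Q1 also rose in both. Padi4 fell from 19.6 CPM to 0.933 and 1.09, and the peptide transporter Slc15a2 from 35.2 to 4.64 and 2.65. Mtus2 and Ccl21a, a chemokine of lymphoid stroma, also fell in both. For each of these genes the summed level of both knock-outs lay beyond that of both wild-type leukemias. Srgap3, Necab1 and Hes5 fell in both too, but stood at 1.56, 7.49 and 1.30 CPM in WT0 with PBS, at or below the knock-out levels.

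In both comparisons 1819 genes rose (1426 expected of independent calls) and 2804 fell (1871 expected), while 2530 moved in opposite directions (3266 expected). Unchanged groups simulated against the same WT6 libraries with the spread between leukemias shared more genes, 3686 higher and 3730 lower on average, with 2710 in opposite directions, and with the spread between libraries they shared 0. The fold changes correlated at r = 0.468 and rho = 0.256 across genes. Both comparisons share the WT6 libraries, and unchanged groups simulated against them gave r = 0.449 with the spread between libraries and 0.497 with that between leukemias. The covariance of 0.39 lay above the simulated 0.0116 for the spread between libraries and below the 0.438 for that between leukemias. With disjoint wild-type controls the shared genes numbered 2371 (3652 expected) and 2220 (3306 expected), and the correlation turned negative. It was r = -0.246 (rho = -0.333) for KO7 against WT6 and KO3 against WT0 with PBS and r = -0.158 (rho = -0.337) for the reverse, while unchanged groups gave 0.000766 with the spread between libraries and 0.00168 with that between leukemias.

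To compare genotypes with leukemias as the replicates, counts were summed per leukemia. In this comparison 0 genes passed in edgeR, with 226 of 17226 at an unadjusted p under 0.05 (861 expected) and a smallest adjusted p of 0.928. DESeq2 called 46 genes (403 unadjusted) and limma-voom 0 (200 unadjusted). Bcat1 had a log2 of -2.53 in the knock-outs (SE 0.71, edgeR adjusted p = 1), with both knock-outs below both wild types. The granzyme Gzmb had a log2 of 3.39 (edgeR adjusted p = 1), and adjusted over the list alone it was the 1 NOTCH1 target that passed. Cyp39a1 (log2 3.11), Mid1 (2.23), Ifi208 (2.36), Ace (1.99) and Padi4 (-3.52) were also among the genes with the smallest p-values. Summed levels of both knock-outs lay apart from those of both wild types for 20.2% of 15948 genes, against 33.3% by chance and 38.3% and 41.4% for the other pairings of the 4 leukemias. By at least 2-fold, 46 genes lay higher and 72 lower in the knock-outs (118 in all), against 351 and 701 genes apart in the other pairings. Unfolded protein response genes, lower in each knock-out than in WT6, had a median log2 of -0.18 here (camera adjusted p = 0.268, adjusted p = 0.999 with an estimated correlation), with Xbp1 at 75.8 CPM in WT0 with PBS against 131 in KO7. With the preset correlation 6 lists passed camera: B cell markers (adjusted p = 2.41e-06), oxidative phosphorylation (8.06e-06), platelet markers (0.0005), macrophage markers (0.00376), NRF2 genes (0.0292) and branched-chain amino acid catabolism (0.0292). For each of these the adjusted p = 0.999 with an estimated correlation, and all but the B cell markers failed when at least 1 of the 4 leukemias was left out, as oxidative phosphorylation did without KO3 (0.112).

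The knock-out leukemias were also compared with each other. All 14 erythroid markers were lower in KO3 than in KO7 (median log2 -2.25, camera adjusted p = 2.23e-11), with Alas2 at 357 against 2106 CPM. Macrophage markers were lower in 14 of 17 and higher in 2 (camera adjusted p = 4.19e-06), with Cd5l down by log2 -1.94. MYC and ribosome biogenesis genes were higher in KO3 in 25 of 28 and lower in 2 (camera adjusted p = 4.19e-06), with Npm1 up by 0.64. Genes of G2 and M phase were lower in 22 of 27 and higher in 2 (camera adjusted p = 4.39e-06), with Mki67 at 801 against 1528 CPM, and interferon response genes in 19 of 35, with 7 higher (camera adjusted p = 0.0103). Glycolysis and hypoxia genes were higher in 18 of 26 (camera adjusted p = 0.0202, adjusted p = 0.0982 with an estimated correlation), and B cell markers in 11 of 15 (camera adjusted p = 0.0225, adjusted p = 0.238 with an estimated correlation). NRF2 genes were lower in 14 of 21 (camera adjusted p = 0.0202, adjusted p = 0.151 with an estimated correlation). Branched-chain amino acid catabolism was higher in 17 of 27 (camera adjusted p = 0.0396, adjusted p = 0.0961 with an estimated correlation and 0.0595 with a filter of 1 CPM in 3 libraries). The imprinted RNA H19 (log2 3.80), the Hedgehog effector Gli1 (3.52) and Arg1, an arginase of macrophages (3.42), were higher in KO3. Hormad2 (-6.28) and Mn1 (-4.63) were lower. Heat shock genes had a median log2 of 0.18 and a mean of -0.21 (camera adjusted p = 0.14). In all, 5757 genes were higher and 5513 lower by edgeR, 1163 and 1962 of them by at least 2-fold.

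The wild-type leukemias WT6 and WT0 with PBS, both with intact Bcat1, gave the background of leukemia-to-leukemia difference. They also differed in sex-linked genes, with Xist at 322.5 against 4373 CPM and the Y-linked Ddx3y at 88.1 CPM against 0 counts. All 27 G2 and M phase genes were lower in WT6 (median log2 -0.54, camera adjusted p = 1.44e-10), as were 24 of 25 S phase genes (camera adjusted p = 1.16e-08), with Mki67 at 861 against 2142 CPM. Unfolded protein response genes were higher in 16 of 17 with 0 lower (median log2 0.81, camera adjusted p = 6.6e-09) and ATF4 genes in 22 of 27 with 1 lower (camera adjusted p = 2.47e-05), with Xbp1 up by log2 1.69 and Ddit4 by 1.38. Interferon response genes were lower in 24 of 35 and higher in 7 (camera adjusted p = 0.000141), with Rsad2 down by log2 -2.32. All 14 erythroid markers were lower (median log2 -1.85, camera adjusted p = 2.83e-10), all 13 neutrophil markers higher (camera adjusted p = 2.6e-06), 10 of 12 dendritic cell markers higher (camera adjusted p = 0.000453) and 18 of 24 mature T cell genes higher with 5 lower (camera adjusted p = 0.000282). The coreceptor Cd8a rose from 164 to 870 CPM and Igkc from 434 to 5791 CPM.

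A further 8 lists passed with the preset correlation and not with the estimated one. These were MHC class I presentation (adjusted p = 0.0535 with an estimated correlation), DNA repair (0.0507), p53 targets (0.0535), macrophage markers (0.0551), immediate early genes (0.105), the BCL2 family (0.122), NK cell markers (0.168) and MYC and ribosome biogenesis (0.0701). The last also missed the threshold without WT6 replicate 2 (camera adjusted p = 0.0502) or replicate 3 (0.0506). Among genes with a mean of at least 5 CPM, leaving out receptor, immunoglobulin and sex-linked genes, large differences were seen in the macrophage products Retnla (log2 7.65) and Arg1 (5.99), the chemokine Ccl8 (6.03) and Prss2 (-4.30). In all, 5875 genes were higher in WT6 and 5683 lower by edgeR, 1459 and 1554 of them by at least 2-fold.

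To compare the inhibitor with the knock-out, fold changes with ERG-245 were set beside the mean of both knock-outs against WT6. Neutrophil markers fell with ERG-245 and in both knock-outs against the shared WT6, which had the highest share of them (0.0384% of counts). The shares in KO7 (0.0147%) and KO3 (0.0207%) lay above that in WT0 with PBS (0.00782%), and across leukemias their median log2 was -0.28 while camera's direction was upward (camera adjusted p = 0.497). Redox genes of the NRF2 list passed camera upward with ERG-245 and in both knock-outs against WT6. In KO3 their mean log2 was 0.01, with an adjusted p = 0.114 with an estimated correlation. Across leukemias that p was 0.999, and the preset call was lost without WT6 (0.276), KO7 (0.813) or WT0 with PBS (0.0508). The unfolded protein response had 12 members higher and 3 lower with ERG-245 and fell in both knock-outs against WT6, while across leukemias it had a camera adjusted p of 0.268. The immunoglobulin share of counts moved the same way. It was 0.246% with PBS and 0.794% with ERG-245, and 2.63% in WT6 against 0.794% in KO7 and 0.795% in KO3. Across genes the correlation was r = -0.0557 and rho = 0.063. With KO7 alone it was r = 0.0502 and with KO3 alone r = -0.164, and without immunoglobulin, receptor, erythroid, neutrophil and platelet genes r was 0.0306. With KO3 against KO7, leukemias of the same genotype, it was r = -0.196 and rho = -0.246, larger in size than with either knock-out against WT6. Of genes called in both, 2015 were higher in each (1574 expected of independent calls) and 2040 lower in each (1719 expected). A further 1599 were higher with ERG-245 and lower in the knock-outs (1731 expected), and 1473 the reverse (1562 expected). Correlations across genes carry no p-value here, since genes are not independent replicates.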

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

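The comparison of KO3 with KO7 was planned before the data were examined, and the count of opposite genes and the choice of lists in this part were made after the result was seen. Relative to WT6, 113 genes changed at least 2-fold in opposite directions in KO7 and KO3 and also passed between KO3 and KO7 (edgeR, adjusted p under 0.05). Opposite changes of that size already set KO3 and KO7 apart, so passing between them is no further support. In the same direction by at least 2-fold, 176 genes rose and 664 fell in both. The opposite genes drew attention because both groups carry the same genotype under the same contrast. Among them, Dpf1 had a log2 of 2.04 in KO7 and -1.93 in KO3, and H19 had -2.03 and 1.77.

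MYC and ribosome biogenesis genes fell in KO7 in 19 of 28 and rose in KO3 in 25 of 28, and this difference between the knock-outs had a camera adjusted p of 4.19e-06. The fall in KO7 had an adjusted p = 0.0515 with an estimated correlation. Macrophage and monocyte markers rose in KO7 in 13 of 17 and fell in KO3 in 11 of 17, again with a camera adjusted p of 4.19e-06 for the difference. The fall in KO3 had an adjusted p = 0.0904 with an estimated correlation.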

How the results depend on the processing

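The fits without receptor, immunoglobulin and other-cell marker genes, with the ERG-245 libraries in place of the PBS ones across leukemias, and of the ERG-245 sum against both wild-type sums were chosen only after the result was seen, and all other alternatives were planned. The counts of the 5 comparisons between groups stayed within 1.5 times of the reported value under all alternatives but the one named next, from 9461 to 10461 for ERG-245, 10127 to 11214 for KO7, 8441 to 9550 for KO3, 10535 to 11479 for KO3 against KO7 and 10864 to 11874 for WT6 against WT0 with PBS. With ERG-245 as 1 summed sample against the sums of WT0 with PBS and WT6, and the spread between leukemias, the count was 0 in edgeR. The treated side has n = 1 and the control differs, so this count cannot be compared with the 10488 genes against PBS. Those 10488 rest on the spread between libraries, which may be technical. The labels give both of their groups the same single leukemia number, so no leukemia is replicated there either. The split by direction depended on scaling. By library size alone the share of called genes that were higher went from 50.2% to 41.5% for ERG-245, 46.8% to 39.5% for KO7, 46.4% to 43.5% for KO3, 51.1% to 56% for KO3 against KO7 and 50.8% to 57.7% for WT6 against WT0 with PBS. With the 2 groups alone it was 49.6% for KO7 and 50% for KO3; the cause was not tested. Of 11219 values of named genes under alternatives, all had the same sign and 11204 were still past the threshold. Bcat1 stayed at 2.08 to 2.09 CPM in KO7 and 6.94 to 7.15 in KO3.

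Across leukemias, where edgeR called 0 genes, 8 passed with no filter, 46 with DESeq2 and 3 with a random leukemia block in limma-voom. With a leukemia left out, 7 passed without WT6 and 3 without WT0 with PBS. The 7 were Trbv3, Trbv17, Trbv19 and the Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y. The 3 were Trbv2, Trbv19 and the immunoglobulin segment Igkv4-68. With no filter, Trbv2, Trbv17 and Trbv19 passed beside unnamed gene models. DESeq2 called receptor and immunoglobulin segments and Xist, beside other genes such as Gzmb and Cyp39a1. The Y-linked genes had 0 counts in WT0 with PBS, the only wild type left without WT6. They stood at 32.4 to 94.5 CPM in WT6, 30.2 to 112 in KO7 and 33.8 to 89.1 in KO3. These values argue against genotype as the cause of the Y-linked calls. The cause of the other calls was not tested. With libraries as replicates 9419 passed, and 9339 with a replicate block as well, since that setting takes the spread between libraries in place of that between leukemias. The overlap of both knock-outs was 2371 and 2220 with disjoint controls and 840 at 2-fold. The correlation of inhibitor and knock-out changed sign with KO7 alone (0.0502) and without immunoglobulin, receptor, erythroid, neutrophil and platelet genes (0.0306), and was -0.164 with KO3 alone. With an estimated correlation 8 lists passed for ERG-245, 11 for KO3 against WT6, 5 for KO3 against KO7, 9 for WT6 against WT0 with PBS and 0 across leukemias. With fry, which does not compare a list with other genes, 31 passed for ERG-245, 30 for KO7, 30 for KO3, 30 for KO3 against KO7, 31 for WT6 against WT0 with PBS and 0 across leukemias. Across leukemias 15 lists passed without WT6 and 10 without WT0 with PBS. Depth limits genes near the floor of 3 counts per group, and the 4 leukemias limit the genotype test, in which a simulated 2-fold change was recovered for 1.49% of genes, a 4-fold change for 47% and an 8-fold change for 74.2%.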

Other observations

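The splits of libraries were planned, whereas the split of leukemias and the tests of clones, leukemic-cell share, erythroid share, carry-over, erythroid cells, macrophages and Xist were chosen only after the result was seen, as were the single genes named in this part. T cell receptor constant genes differed among groups as the V segments did. Trbc2 led over Trbc1 in WT0 with PBS (924 against 166 CPM), WT6 (718 against 299) and KO7 (1510 against 137), while Trbc1 led in WT0 with ERG-245 (852 against 680) and KO3 (1600 against 1230). Trgc2, a gamma constant gene, stood at 318 CPM in WT6, 144 in WT0 with PBS, 90.1 in KO7, 36.1 with ERG-245 and 0.949 in KO3. The delta segment Trdv5 stood at 59.0 CPM in KO3 and at 0.41 to 4.32 in the other groups. The trypsinogen gene Prss2 lies on chromosome 6 at 41521776 to 41525079, between the start of Trbv17 at 41163092 and that of Trbc1 at 41538219. It stood at 123 CPM in WT0 with PBS, where Trbv17 led, at 6.27 in WT6, at 2.04 with ERG-245 and at 0 counts in KO3, which allows up to 0.048 CPM.

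Several genes that stand in no erythroid list were higher in WT0 with PBS and KO7 than in WT6 and KO3, the groups with more and with less erythroid RNA. Lmo2, a transcriptional partner in T cell leukemia and in red cell precursors, stood at 146, 170, 52.3 and 48.8 CPM in that order of groups. Bcl2l1, an inhibitor of apoptosis, stood at 135, 229, 89.8 and 69.1 CPM, and Gpx1 at 1245, 1675, 440 and 509 CPM. Slc6a9, a glycine transporter, stood at 142 CPM in KO7, 25.8 in WT6 and 26.2 in KO3.

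The ERG-245 and PBS libraries of WT0 differed in 10488 genes. Against a different share of leukemic cells as the whole cause, platelet markers fell to a median log2 of -3.97, and of 8 lists of other-cell markers 2 passed upward and 2 downward with an estimated correlation. A candidate explanation is that the libraries hold different leukemic clones, since Trbv17 held 39.7% of TRBV counts with PBS and 0.93% with ERG-245. The action of the inhibitor, which the design names, also stays open. Clone and treatment go together in these groups, so no test here separates them.

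Other splits of the samples were fitted for each comparison. For the comparisons between groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with real values of 10327 for ERG-245, 10687 for KO7, 9368 for KO3, 10975 for KO3 against KO7 and 11419 for WT6 against WT0 with PBS, and a highest other value of 0 for each. These splits are too few for a share under 0.05. For knock-out against wild type across leukemias, 3 of the 3 splits gave as many genes as the real one, which gave 0, and the highest other gave 166. These splits too are too few for a share under 0.05.

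The split with 166 genes sets WT0 with PBS and KO7 against WT6 and KO3, with 164 of them higher in the first pair, and so points to a structure of the samples other than genotype. A different share of erythroid cells may account for part of it. Erythroid markers differed by a median log2 of 2.16 in this split (camera adjusted p = 2.05e-17, adjusted p = 0.933 with an estimated correlation), and 7 of the 166 genes are erythroid markers. What else separates these pairs stays open, and no biological explanation was tested.

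Bcat1 counts remained in both knock-outs, at 5.92% of WT6 in KO7 and 19.7% in KO3. Against carry-over of reads or cells from the wild-type libraries, their leading V segments reached at most 0.0563% of their wild-type level in a knock-out. Against erythroid cells as the source, the KO3 to KO7 ratio was 0.198 for their marker share but 3.33 for Bcat1, and all 14 markers were lower in KO3. Macrophages and monocytes as the source stay open. They were first tested together with erythroid cells on marker shares alone, which argued against both, and were tested apart after the single genes had been seen. The ratio was 0.446 for their marker share, with 14 of 17 markers lower in KO3 and 2 higher, but Lyz2 stood at 171 CPM in KO3 against 53.6 in KO7, Ccl8 at 81.7 against 15.8, Arg1 at 34.0 against 3.18 and Retnla at 28.7 against 3.72. Against other cells that carry Xist, in the same mixture in both knock-outs, the ratio for Xist was 1.96 (1.88 to 2.03 over pairs of libraries), outside the 2.31 to 5.31 of Bcat1. This explanation was put to the test in more than 1 form, including a looser bound (a ratio for Xist below 1) under which it stayed open, and each form was set after related values had been seen. Some values of other lists ran the other way. NK cell markers held 0.0465% of counts in KO3 against 0.0186% in KO7. As a list, however, 1 of 7 NK cell markers was higher and 2 were lower (camera adjusted p = 0.801). Neutrophil markers held 0.0207% against 0.0147%, with 9 of 13 higher and 1 lower. B cell markers were higher in KO3 in 11 of 15 genes though lower in share (0.249% against 0.378%). Other cells and mixtures of cells therefore stay open, and so do transcripts of a part of the gene that the deletion may leave, since the labels do not say which exons are deleted and the counts cover the whole gene.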
